A study of Homo sapiens with 18 samples.

How the data were processed

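The deposited tables analysed here list RNA sites found with hnRNP C PAR-CLIP and PARCLIP-MeRIP in HEK293T cells. The 18 samples were assigned to 9 groups of 2 from their titles. Nothing in the labels ties the replicates to separate cultures. Per the submitters' processing notes, Trimmomatic, Bowtie 1.0.0 and the hg19 genome were used, with TopHat 1.1.4, Cufflinks, Cuffdiff and DESeq also named by the authors for the RNA-seq samples. The order of these steps, how sites were called, the thresholds, any treatment of reads that align to repeats, and whether replicates were pooled are not given in the sources used here.

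Per the file headers, each entry of the deposited lists gives a U-tract and an RRACH motif with their positions, the U-tract length and the distance between them. The HCS list also gives exon or intron. The lists hold no counts, enrichments or p-values, so depth per sample is unknown and no test between samples could be run. Intervals of shares are exact binomial or bootstrap intervals at 95% and leave out errors of site calling. The intended results on hnRNP C occupancy in both METTL knockdowns and on RNA abundance in each knockdown, and the naming of sites by their fold change, were therefore not run.

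The switch list held 17352 entries and the HCS list 2798. Entries were reduced to distinct U-tracts (chromosome, strand, start and end), giving 13378 and 2748 sites, or 15024 in either list. A U-tract in the Y chromosome that copies an X chromosome site was counted once, which removed 3. Gene symbols were taken from the lists. Some entries carried a calendar date in place of a symbol, and each such date was counted as a gene. Where a symbol was missing, it was looked up by transcript in a RefSeq gene table of GRCh38, which gave 753 of 756 in the switch list and 4 of 4 in the HCS list. For 6 looked-up genes the lists also use an older symbol, and each was counted once. That table was used for names only, and all positions are hg19. The listed U-tract length equalled end minus start plus 1 in every entry. The listed distance is the edge-to-edge gap for a downstream motif, and for an upstream motif it includes the 5 nt of the motif, which was checked against the positions of every entry. The edge-to-edge gap was used where the text says gap.

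Genes that share a listed site were joined to 4331 loci, which served as the unit of resampling. Intervals came from 1000 bootstrap draws of loci. The region test shuffled the listed status of whole loci between loci with the same number of HCS sites, and a separate test shuffled labels within genes, each with 100000 permutations. The distance test within genes used 10000 permutations, and the spacing test 1000 random placements. Gene lists were tested by 10000 draws of genes matched on bins of switch-site number, with Benjamini-Hochberg adjustment over 12 lists. Tests are two-sided except for spacing, which asks for more close neighbours than random.

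Before the data were examined, the groups, the main tests, the gene lists, most alternatives and the rule for named genes were fixed. Comparisons added afterwards were the downstream share, the U-tract lengths, the share of gaps of at most 10 nt, the tests within genes and the rho drawn at a single rate. The rule took the 10 genes with the most HCS sites (ties by switch sites, then alphabet) and the 10 with the most switch sites, HNRNPC, METTL3, METTL14 and MALAT1. It also took up to 4 members of each list with the most HCS sites and up to 5 genes with at least 20 switch sites and no HCS site. Some genes that the rule takes are not reported here. The region comparison departs from the fixed design. It was to set the HCS sites against the other switch sites, but the switch list carries no region, so HCS sites in and outside the switch list were compared. The distance comparison was to use shifted positions, which needs the hg19 sequence, not used here. It sets HCS sites against the other switch sites in their place. The HCS list was expected to be part of the switch list and is not, as used here.

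The tests were tried on simulated data built on the real sites, in 20 runs each. With no effect, 1, 1 and 1 of 20 runs gave p under 0.05 for the region, distance and list tests, and with an odds ratio of 2, a difference of -4 nt or a list ratio of 2 all 20 did. The medians were then 2.09, -3.95 and 1.75. The simulated list held 200 genes, more than any list tested here, so this power does not carry over to the shorter lists. Labels and gaps of sites were drawn without regard to genes, so the runs do not check for dependence between sites of a gene. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.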

Results

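The study measured where hnRNP C meets methylated RNA in HEK293T cells, a human embryonic kidney line widely used for transfection. hnRNP C is a nuclear RNA-binding protein that prefers runs of uridines, and METTL3 and METTL14 form the enzyme that writes N6-methyladenosine (m6A). The 18 samples fall into 9 groups of 2. PAR-CLIP, which maps protein contacts after crosslinking, was done for hnRNP C in control, METTL3-knockdown and METTL14-knockdown cells. In PARCLIP-MeRIP the crosslinked RNA was also enriched with an m6A antibody, with input and enriched groups. RNA-seq covered control, HNRNPC, METTL3 and METTL14 knockdown cells.

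The values analysed here were 2 lists of RNA sites, with no value per sample. Each entry pairs a tract of at least 5 uridines (a U-tract) with an RRACH motif, the short consensus in which m6A is written, no more than 50 nt away. The first list holds switch sites from PARCLIP-MeRIP and is called the switch list. The other is named HCS by the submitters and is called the HCS list. Read depth is unknown for these lists, and intervals cover counting error only, or sampling of loci where a bootstrap is named. Changes in hnRNP C occupancy or RNA abundance after knockdown were not analysed here.

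The first comparison asked how the lists relate. HNRNPC itself, on the minus strand of chromosome 14, held 30 switch sites and 4 HCS sites, all 4 intronic. Of these, the HCS U-tracts at 21720947 to 21720951 and 21731531 to 21731535 (hg19) were also in the switch list, and those at 21718906 to 21718910 and 21718922 to 21718926 were not. MALAT1, a nuclear long noncoding RNA, held 12 switch sites and 3 HCS sites, and all 3 were exonic and in both lists. They lie on the plus strand of chromosome 11 at 65268479 to 65268490, 65270090 to 65270100 and 65271083 to 65271087, with tracts of 12, 11 and 5 uridines. METTL14 held 3 switch sites and 2 HCS sites, both also in the switch list. On the plus strand of chromosome 4, the one at 119626898 to 119626902 was exonic and the one at 119630490 to 119630494 was intronic. METTL3 held 3 switch sites and 0 HCS sites.

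**Figure D1:**
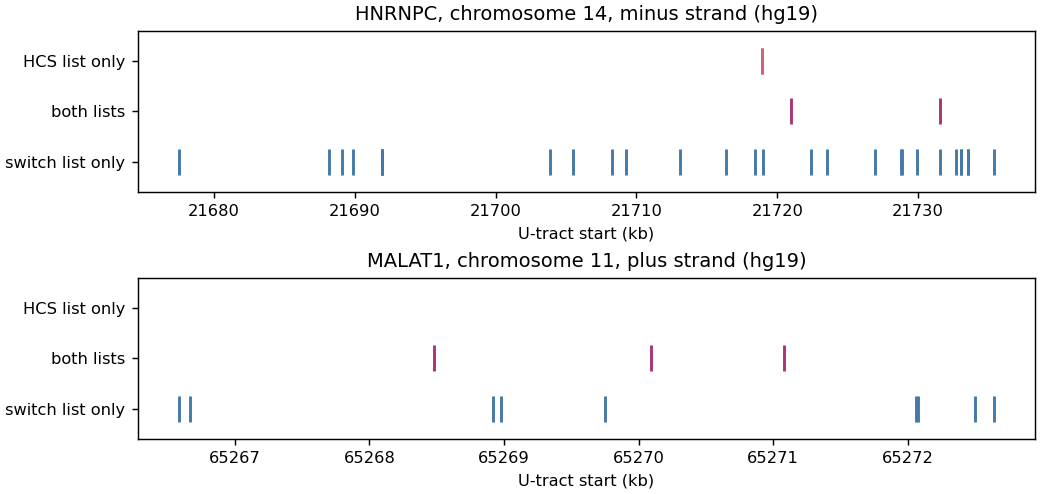
U-tract start positions (kb, hg19) in HNRNPC and MALAT1, with a tick per U-tract placed by the list that holds it. The 3 MALAT1 HCS sites are in both lists, while 2 of the 4 HNRNPC HCS sites are in the HCS list only and lie too close to be drawn apart.

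The switch list held 13378 distinct U-tracts with 11445 RRACH motifs in 4188 genes, and the HCS list held 2748 U-tracts with 2675 motifs in 1816 genes. Of the HCS sites, 1102 (40.1%, exact binomial 95% interval 38.3% to 42.0%) shared at least 1 base with a switch site, and every such pair was the same U-tract. After the HCS sites were moved by 1000 nt upstream or downstream along the chromosome, 5 and 8 of them met a switch site. The other 1646 HCS sites were mostly in the same genes, since 1349 of them (82.0%, interval 80.01% to 83.8%) lay in a gene with a switch site. Close neighbours were rarer, with 43 (2.61%) having a switch site within 100 nt and 261 (15.9%) within 1000 nt. The HCS list as used here is therefore not contained in the switch list. Whether the switch list as used here is complete is not known, and missing entries would lower the overlap. Chromosome 1 held the most sites of both lists, with 12.7% of switch sites and 12.8% of HCS sites.

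The next comparison asked whether exonic and intronic HCS sites were in the switch list equally often. The 9 HCS sites of PTBP2, a splicing repressor of the polypyrimidine tract-binding family, comprised 2 exonic and 7 intronic sites. Its exonic U-tracts, at 97279049 to 97279056 and 97279058 to 97279062 on the plus strand of chromosome 1, were both in the switch list and share an RRACH motif. PITPNB, a phosphatidylinositol transfer protein, held 2 exonic HCS sites on the minus strand of chromosome 22, at 28248359 to 28248363 and 28248413 to 28248419, and both were in the switch list. In POLA1, the catalytic subunit of DNA polymerase alpha on the X chromosome, the exonic site at 24948615 to 24948619 was in both lists and that at 24751895 to 24751899 was in the HCS list only.

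Over all genes, 467 HCS sites were exonic and 2281 intronic (83.0%, exact binomial interval 81.5% to 84.4%). The switch list held 271 of the exonic sites (58.0%, interval 53.4% to 62.5%) and 831 of the intronic sites (36.4%, interval 34.5% to 38.4%). The odds ratio was 2.41 (bootstrap interval over loci 1.96 to 2.99). In a two-sided permutation test that moved listed status between loci, p was 1e-05, the smallest that 100000 permutations can give. Within the 141 genes that hold both kinds of HCS site, exonic sites were listed more often by 25.4 percentage points (odds ratio 2.79, two-sided permutation p = 2.0e-05, 424 sites). Exonic and intronic HCS sites had similar U-tracts, with 66.4% and 66.7% of them 5 nt long. The region of the switch sites outside the HCS list was not given, so the share of exonic sites there was not analysed here.

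**Figure D2:**
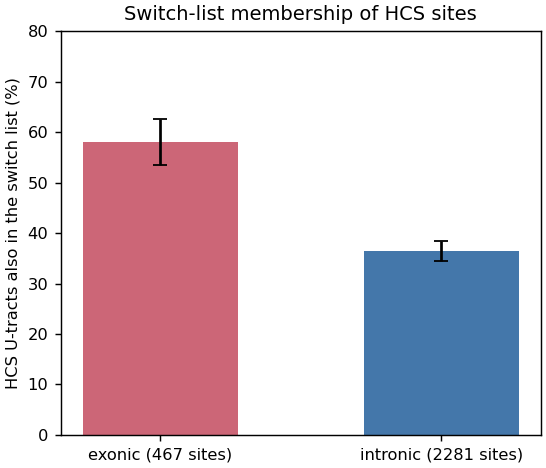
Share of HCS U-tracts (%) that are also in the switch list, for exonic and intronic sites, with exact binomial 95% intervals as error bars. The bars stand at 58.0% of 467 exonic sites and 36.4% of 2281 intronic sites.

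A further comparison asked how far the U-tract lies from its RRACH motif. HCS sites lay nearer, with a median listed distance of 13 nt (bootstrap interval 13 to 14), against 20 nt (interval 19 to 20) for the 12276 switch sites outside the HCS list. In MALAT1 the listed distances of the 3 HCS sites were 15, 4 and 6 nt. Their gaps were 15, -1 and 1 nt, where -1 stands for an overlap by 1 base. In METTL14 the exonic HCS site had a listed distance of 13 nt (gap 8 nt). The pair of exonic sites in PTBP2 had listed distances of 14 and 23 nt (gaps 9 and 18 nt). The motifs of these METTL14 and PTBP2 sites lie upstream, so the listed distance includes the motif. HCS sites in the switch list and those outside it had medians of 14 and 13 nt.

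The difference in medians was -7 nt (HCS minus other, bootstrap interval -7 to -5), and the difference in means was -4.54 nt (interval -5.13 to -3.94). Within the 1372 genes that hold both kinds of site the mean difference was -4.07 nt, with a two-sided permutation p of 1e-04, the smallest possible with 10000 permutations. The edge-to-edge gap was at most 10 nt in 48.6% of HCS sites (interval 46.7% to 50.5%) and in 33.4% of the others (interval 32.5% to 34.3%). The motif lay downstream of the U-tract in 56.0% of HCS sites and 60.0% of the others, a difference of -4.04 percentage points (interval -6.30 to -1.76). Without the downstream gaps of 5, 13, 40 and 48 nt, at which the switch list has high bars, the difference was -2.29 points (interval -4.47 to -0.250). The limit of 50 nt on the listed distance ends upstream gaps at 45 nt, and with gaps of at most 45 nt on both sides it was -3.05 points (interval -5.10 to -0.895). These changes were not combined. U-tracts of exactly 5 nt made up 66.7% of HCS sites and 63.7% of the others, a difference of 2.998 points (interval 0.789 to 4.99). For U-tracts of 8 nt or more the shares were 8.84% and 9.75%, and the interval of their difference (-2.10 to 0.312 points) included 0. No distances at shifted positions were computed, so these values compare listed sites with listed sites.

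**Figure D3:**
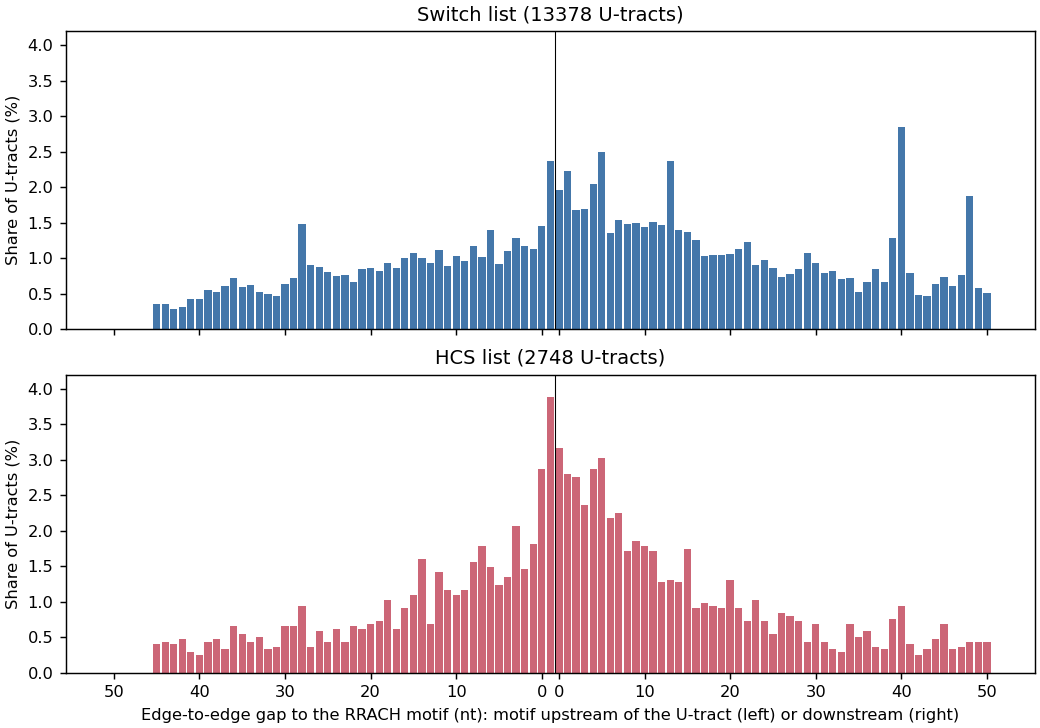
Share of U-tracts (%) at each edge-to-edge gap (nt) to the RRACH motif, for the switch list and the HCS list, with motifs upstream on the left and downstream on the right. The HCS sites gather at short gaps (48.6% at 10 nt or less), and the switch list has single high bars, the highest with 381 sites at a downstream gap of 40 nt.

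Genes were then compared by the number of sites they hold. The genes with the most HCS sites were PTBP2 with 9, and POLA1, PITPNB and the Polycomb-group gene SFMBT2 with 8 each. KANSL1, a scaffold of a histone acetyltransferase complex, the ubiquitin ligase UBE3C and the RNA-binding protein LARP4B held 7 each. ANKRD11, a chromatin regulator, the histone chaperone NAP1L4 and the poly(C)-binding protein PCBP2 held 6 each. Other genes, among them LUC7L2 and SETD2, also held 6, and the tie was broken by the number of switch sites. By switch sites, ANKRD11 led with 42, and NAP1L4 held 31. HNRNPC and the long noncoding RNA FTX held 30 each. POLA1, PTBP2, the secreted guidance factor SLIT2 and the vesicle-tethering protein TRAPPC8 held 28 each, and the read-through gene RPS10-NUDT3 held 27. Of the 31 genes with at least 20 switch sites, UBE2K, a ubiquitin-conjugating enzyme with 21, was the one without an HCS site.

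For shares by gene, a site listed under several genes was counted once for each of them. On that count, sites were spread over many genes, since the 10 leading genes of each list held 2.22% of switch sites and 2.57% of HCS sites. An HCS site was found in 1534 of the 4188 genes with a switch site (36.6%), and 1241 genes held exactly 1 HCS site. On the same count, the share of switch sites that were also HCS sites was 7.84% in genes with 1 switch site, 7.61% with 2 to 5, 8.69% with 6 to 20 and 8.62% with over 20. The share of genes with any HCS site was 19.7%, 38.6%, 72.1% and 96.4% in the same order. Across the 4188 genes, which are not independent replicates, Spearman's rho between the number of switch sites and the share of them in the HCS list was 0.310 (permutation p = 1e-04, the smallest possible). Drawing every site at the overall rate of 8.15%, again with a site counted once per gene, gave a mean rho of 0.310 (95% range 0.281 to 0.336), so the observed rho was no different from that of a rate equal in all genes.

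Of the 12 gene lists fixed beforehand, those with a gene that had a switch site were compared with genes matched on the number of switch sites. Among hnRNP and PTB proteins, 15 of 22 genes with a switch site had an HCS site, against 12.1 in matched genes (permutation p = 0.233), including PTBP2, PCBP2, HNRNPM with 5 and HNRNPC with 4. Among ubiquitin ligases and deubiquitinases it was 27 of 43 against 20.4 (permutation p = 0.0380, adjusted p = 0.456), with UBE3C at 7 HCS sites and USP9X, BIRC6 and USP10 at 4 each. Chromatin modifiers had 26 of 47 against 22.4 (permutation p = 0.292), with SETD2, a histone methyltransferase, at 6, and SMARCC1 and ATRX at 5 each. The m6A writers, erasers and readers had 7 of 15 against 7.65 (permutation p = 0.937), with the reader YTHDF2 and the writer-complex member ZC3H13 at 3 HCS sites each and IGF2BP1 at 2.

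SR and SR-related splicing factors had 13 of 25 genes with an HCS site against 14.3 in matched genes (permutation p = 0.709), with LUC7L2 at 6 HCS sites and SRPK1 and SRSF4 at 3 each. The core spliceosome had 8 of 28 against 11.8 (permutation p = 0.155), with SNRPD1 and U2AF1 at 2 each. DNA replication and repair had 18 of 38 against 15.9 (permutation p = 0.549), led by POLA1 and then PRKDC, a DNA repair kinase, at 4. Mitosis and cell cycle genes had 19 of 39 against 19.2, with the cohesin subunit STAG1 and the kinase CDK1 at 4 each. Nuclear and snoRNA-host long noncoding RNAs had 9 of 14 against 7.21 (permutation p = 0.3998), with MALAT1 at 3 and FTX, JPX and DLEU2 at 2 each. Cytosolic ribosomal proteins had 12 of 41 against 12.5, with RPS3 at 3, and the ZNF zinc finger genes had 34 of 107 against 33.8, with ZNF638 and ZNF644 at 4 each. None of the 40 tissue-restricted genes of blood, liver, muscle and neurons was in either list. In two-sided draws matched on site number, 0 of the 12 lists passed an adjusted p of 0.05 (Benjamini-Hochberg over the lists) and 1 had an unadjusted p under 0.05. The tissue-restricted list had no gene to draw, so it could not pass, but it counted in the adjustment. With Fisher's exact test, which does not match on site number, 3 lists passed.

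**Figure D4:**
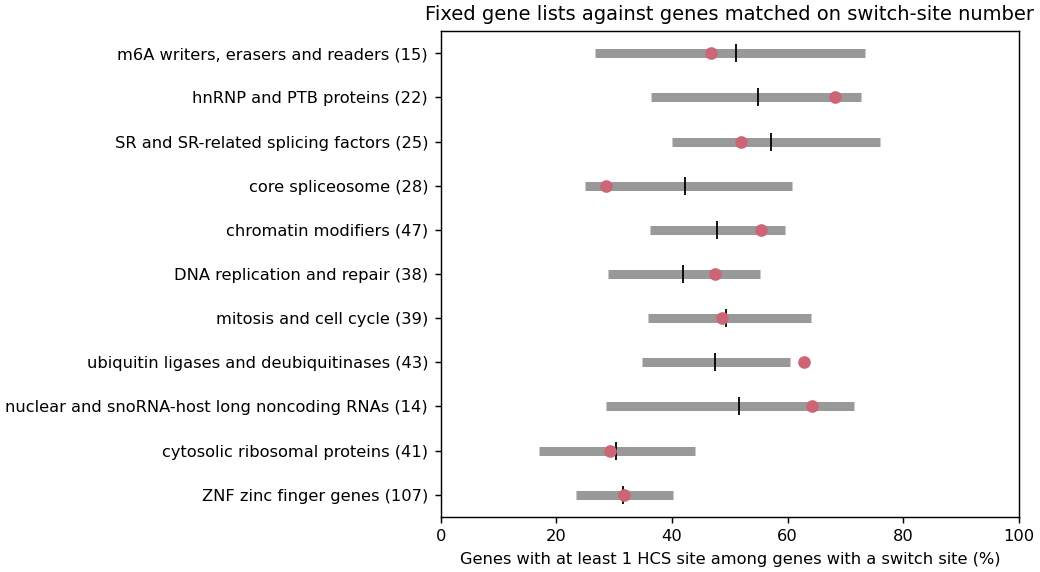
Share (%) of genes with at least 1 HCS site among list members with a switch site (red points), against the mean (black mark) and central 95% range (grey bar) of draws matched on switch-site number, with the number of members in parentheses. The ubiquitin list, at 62.8%, lies outside its range before adjustment, and the list of tissue-restricted genes has no members to draw.

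Neighbouring sites were compared last, because U-tracts that lie close can be a single binding event listed several times. Of the switch sites, 30.6% had another switch site within 100 nt on the same strand, against 0.225% for random positions in the same 1 Mb blocks (permutation p = 0.001, the smallest that 1000 draws allow). Blocks also hold sequence outside genes, and random positions need hold neither a U-tract nor a motif. The small p was therefore built into the comparison and says nothing about grouped binding. Between the first and the last site of each gene the share was 34.7%, against 11.1% for random positions. HCS sites had a neighbour in 6.26% of cases, against 0.0405%. Merging sites within 100 nt left 11194 switch clusters and 2660 HCS clusters. A single RRACH motif was listed with more than 1 U-tract for 1753 motifs of the switch list and 71 of the HCS list, as in PTBP2 and PITPNB. U-tracts that share a motif lie close by construction, since each is no more than 50 nt from it. Much of the share with a neighbour therefore comes from shared motifs.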

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

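These alternatives were chosen after the results were seen: the edge-to-edge gap, 1 U-tract per motif, leaving out the gaps predicted for antisense Alu, gaps of at most 45 nt, leaving out sites listed under more than 1 gene, random positions within a gene's span, and counting for the gene lists only HCS sites that are also in the switch list. With Fisher's exact test without matching on site number, 3 gene lists passed, against 0 with matching. By that exact test they were hnRNP and PTB proteins (adjusted p = 0.0190), chromatin modifiers (0.0373) and ubiquitin ligases and deubiquitinases (0.00763). The alternatives that kept the matching gave 0 lists. The overlap of the lists ranged from 40.1% to 40.9%, the exonic odds ratio from 2.36 to 2.41, and the difference in median distance from -7 to -5 nt, all in the same direction. The downstream share and the share of 5 nt U-tracts, themselves compared only after the data were seen, kept their direction. The difference in downstream share came near 0 without the predicted Alu gaps (-2.29 points). Leaving out these gaps and the limit to 45 nt were not combined, so whether the interval of that difference would then include 0 is not known. The rho by site number was 0.305 to 0.311, but a single rate for every site gives 0.310. No paired analysis was possible because the tables hold no values per sample, so leaving out replicates was not possible either. Alternatives that need scores, sequence (GGACU, DRACH) or the region of every switch site were not run, nor were those for occupancy and RNA abundance. Depth is unknown and its effect on which sites are listed could not be measured.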

Other observations

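The tests of antisense Alu copies, of motifs with a single listed U-tract and of randomly placed motifs were chosen only after the results were seen, as were the alternatives without the predicted Alu gaps and with 1 U-tract per motif. The test of random placement was first made on the whole switch list and was extended to the HCS list after its value was known.

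The exonic share of HCS sites within the gene lists was not tested, and its values follow. Of the HCS sites in nuclear and snoRNA-host long noncoding RNAs, 7 of 16 were exonic, with 3 of them in MALAT1, and in the core spliceosome 5 of 13 were exonic. In ubiquitin ligases and deubiquitinases 4 of 58 were exonic, and the 7 sites of UBE3C were all intronic. Among cytosolic ribosomal proteins, RPL13 held 2 HCS sites, both exonic and both in the switch list, while the 3 sites of RPS3 were intronic. YTHDF2 held 10 switch sites and 3 HCS sites, with 0 of the 3 in the switch list, and the zinc finger gene ZNF850 held 1 switch site and 3 HCS sites.

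Some gaps between U-tract and motif were over-represented in the switch list: the downstream gaps of 5, 13, 40 and 48 nt held 335, 317, 381 and 251 sites. An antisense Alu consensus fragment, compared with the list after these bars were seen, predicts the same gaps. That prediction pools the fragment with forms in which a single CpG is changed to CpA, which leaves more freedom to match the bars. The gaps of 5, 13, 40 and 48 nt held 2.13 times the mean of neighbouring gaps. This ratio restates the bars and is no evidence for copies of antisense Alu elements. Such copies stay open as a possible explanation because repeat annotation and genome sequence were not used here. Among motifs with a single listed U-tract the ratio was 2.82 at 40 nt (interval 2.33 to 3.39), which argues against double listing as the whole cause there. The ratio was 1.27 at 5 nt (interval 1.08 to 1.46), 1.31 at 13 nt (1.11 to 1.53) and 1.61 at 48 nt (1.24 to 2.10). These intervals also lie above equality with neighbouring gaps. However, the gaps were tested after their high bars were seen in the same list, which favours a ratio above equality. Whether double listing is the whole cause at 5, 13 and 48 nt, and how much of the excess it makes up there, therefore stays open. A few loci listed many times are argued against at 40 nt. There 6.30% of the sites lay in the 10 loci with most of them, against 6.03% for sites drawn at random. Gene families with members at different loci were not tested. Of the switch sites at the predicted gaps 4.98% were HCS sites, against 8.91% at neighbouring gaps (odds ratio 0.536, interval 0.384 to 0.720). At 5, 13, 40 and 48 nt the shares were 7.76%, 6.31%, 3.15% and 2.39%, against 10.8%, 9.90%, 4.91% and 6.67% at their neighbours. Shares were lower at the longer gaps on both sides. The pooled values weigh the gaps differently, so part of the pooled contrast comes from that mix. The HCS list itself held 26 sites at 40 nt, against a mean of 12 at neighbouring gaps. At 5, 13 and 48 nt it held 83, 36 and 12 sites, against means of 66.5, 41.25 and 10.75. No biological explanation was tested for these gaps.

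Exonic HCS sites were in the switch list more often than intronic ones. Differences between genes in coverage are argued against as the whole cause, because the odds ratio within genes was 2.79. U-tract length and gap are argued against too, with an odds ratio of 2.40 within strata of both. A difference in read coverage between exons and introns of the same gene may still account for it, and so may the rules by which the lists were made, and neither could be tested without values per sample. Whether the switch list is complete is not known either, and missing entries could also shape this difference. No biological explanation was tested.

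HCS sites lay nearer to their RRACH motif than other switch sites. The difference in medians was -6 nt without the Alu-predicted gaps and -5 nt with 1 U-tract per motif, and the mean difference within genes was -4.07 nt, which argues against each of these as the whole cause. Over gaps of 1 to 45 nt, without the Alu-predicted gaps, an exponential fall of site number with the gap was fitted. Whether this form describes the lists was not tested. HCS site number changed little beyond a gap of 30 nt, so a single rate does not describe the HCS list over the whole range. The fitted rate was 0.0250 per nt in the whole switch list (interval 0.0235 to 0.0265) and 0.0236 in switch sites outside the HCS list (interval 0.0218 to 0.0252). Among HCS sites it was 0.0454 (interval 0.0416 to 0.0490). Motifs placed at random with equal base use would give a rate of 0.0236, but base use was not measured, so this comparison decides nothing for either list. The HCS list may have been made with a rule that favours short gaps, which stays open because the calling rules are not given in the sources used here, and no biological explanation was tested.

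Switch sites 8 nt apart were the most frequent close neighbours, with 436 pairs against 163 pairs at 6 nt. Among motifs with 2 downstream U-tracts, 350 held tracts 8 nt apart, and 214 held tracts at gaps of 5 and 13 or of 40 and 48 nt. This peak and the high bars at those gaps are therefore partly the same sites. The share of HCS sites that were also in the switch list ranged from 31.5% on chromosome 14 (28 of 89) to 49.4% on chromosome 22 (44 of 89). These are the extremes among the chromosomes, and a difference between chromosomes was not tested. An upstream gap of 28 nt held 199 switch sites, and it was not among the gaps tested.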
